A study of Mus musculus with 6 samples.

How the data were processed

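B16-F1 cells, a pigmented melanoma line of C57BL6 mouse origin, were implanted at the dorsal flank of WT mice or of mice lacking Stat2, and the tumours were collected at day 20, per the labels. Total RNA of 6 tumours, 3 from each host genotype, was labelled with biotin and hybridized to Affymetrix arrays, 1 array per tumour. The genotype is that of the host, and the labels do not state that the implanted cells lack Stat2. The labels speak of individual tumours without saying whether each came from its own mouse, so p-values measure the spread between these 6 tumours.

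The deposited values are log2 expression values, 1 per probe set and array, which the authors made with Affymetrix Expression Console 1.3.1 and RMA, per the submitters' processing notes. A genome build is not given in the sources used here, and no coordinates are reported. The number of arrays limits the precision. Probe-level intensities, detection calls and scan dates were not used here, so neither signal over background nor a scan batch could be examined.

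The table holds 41345 probe sets. The platform annotation gives 1 gene for 23521 of them, several genes for 1814 and none for 16010. Of the probe sets with 1 gene, 23328 had a gene identifier in the reference gene table and 193 had not, and 0 symbols changed when they were updated through it. Each gene was represented by its brightest probe set, by the mean over all 6 arrays, among those naming only that gene. This gave 22180 genes, of which 1082 had more than 1 such probe set. No gene was named from a probe set with several genes, and no filter on dim probe sets was applied. Probe sets of close paralogs, as in the Ifi200 family and the olfactory receptors, can hybridize to more than 1 transcript.

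Differences were computed as Stat2 KO host minus WT host on the log2 scale with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. All SEs of differences and all adjusted p-values of genes come from this fit. The residual degrees of freedom were 4 and the prior degrees of freedom 8.139. Single values were also compared by exact two-sided permutation of the 6 arrays, which cannot give a p below 0.1.

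Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists with at least 5 measured members. Beside it stand camera with a correlation estimated from the arrays and fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move one way on balance. The 21 lists cover type I interferon response, interferon gamma response, MHC class I and class II presentation, inflammatory cytokines and chemokines, cell cycle, hypoxia and glycolysis, and immediate early and heat shock genes. The others hold markers of T cells, NK cells, B cells, dendritic cells, macrophages, neutrophils, endothelial cells, fibroblasts, melanocytes, keratinocytes, skeletal muscle, adipocytes and red blood cells. They hold 418 genes, 386 of them measured by a probe set of their own, and 0 genes stand in more than 1 list. Each list's median was also placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Genes of the random lists were drawn one by one, without regard to whether they vary together. The matched ranges therefore account for expression level only. They leave out the spread between tumours that correlated genes of a list share, so a median outside its range does not by itself show an effect of host genotype.

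The genes named were fixed by a rule. Stat2 comes first, followed by the 10 genes with the largest difference in each direction among those past the threshold whose groups do not overlap. Open places went to genes with an unadjusted p under 0.01, groups that do not overlap and a mean expression above the median of all genes. Of each list, up to 4 members with the smallest p could be named. The rule passed over 7 predicted transcripts. The design, the lists, the naming rule and all alternatives except cyclic loess were set before the data were examined.

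The alternatives were the replicate number as a block, a further quantile normalization, median centring, only genes brighter than the median gene, the mean of all probe sets of a gene, all probe sets, eBayes without the trend or robust, array weights, other thresholds, the other list tests, and each array left out in turn. Cyclic loess normalization was added after the first results had been seen.

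The procedure was tested on simulated data with 22180 genes and the array numbers of this comparison. It recovered 98 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2 units, with 18 false among 216 calls. In 20 simulated data sets with independent genes and 1 list lowered by 0.35, a log2 change of -0.35, camera found that list in 20 with the preset and in 15 with the estimated correlation. Of 380 unchanged lists, 2 were called with the preset and 0 with the estimated correlation. All simulated genes were independent, whereas the correlations estimated from the arrays ranged from 0.0405 to 0.659 over the tested lists. These lie above the preset of 0.01, so the simulation does not give the rate of false list calls in these data.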

Results

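Expression was measured in 6 B16-F1 melanoma tumours at day 20, 3 grown in WT hosts and 3 in hosts without Stat2. Median log2 values of the arrays were 6.08, 6.22 and 6.17 for the Stat2 KO hosts and 6.06, 6.06 and 6.13 for the WT hosts, in replicate order. Correlations between pairs of arrays ranged from 0.964 to 0.986 across genes, and 0 pairs of arrays held identical values.

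The comparison of Stat2 KO with WT hosts asks how a tumour's gene expression differs when the host cannot make STAT2, a transcription factor that switches on genes after type I interferon. The submitters' design text describes larger tumours in the hosts without Stat2. Stat2 itself read 6.42 ± 0.077 in Stat2 KO hosts and 6.73 ± 0.053 in WT hosts (log2, mean ± SD, n = 3 each), a difference of -0.31 (SE 0.126), or 19.4% lower. Its 3 values were 6.45, 6.48 and 6.33 in Stat2 KO hosts and 6.79, 6.70 and 6.70 in WT hosts. All Stat2 KO tumours lay below all WT tumours (exact permutation p = 0.1, the smallest possible with 3 against 3), and the limma adjusted p was 0.532. The melanoma cells are not labelled as lacking Stat2, and the part of the gene that the single Stat2 probe set covers is not given in the sources used here, so this level is a weak check of the labels.

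Ifi204 and Cxcl9 fell in tumours of Stat2 KO hosts, and both are interferon-induced. Ifi204, a member of the Ifi200 family of nucleic acid sensing proteins, fell by 1.75 log2 units (SE 0.200, limma adjusted p = 0.0298), from 4.89 ± 0.084 in WT to 3.14 ± 0.332 in Stat2 KO hosts (n = 3 each). Cxcl9, a chemokine that attracts activated T cells through CXCR3, fell by 1.69 log2 units (SE 0.209, limma adjusted p = 0.0338), from 7.84 ± 0.467 to 6.15 ± 0.204 (n = 3 each). All 3 Stat2 KO tumours lay below all 3 WT tumours for both genes. Ifi204 has close paralogs, and both its group means lay below 5.21, the median level of olfactory receptor genes, which tumours are not known to use. Its probe set was therefore not shown to read above background in either group, and the size of its difference is uncertain. Its adjusted p was 0.169, 0.0735, 0.109 and 0.130 without Stat2 KO replicate 1, Stat2 KO replicate 2, WT replicate 1 and WT replicate 2. That of Cxcl9 was 0.271, 0.0735, 0.175 and 0.109 without Stat2 KO replicates 1, 2 and 3 and WT replicate 1. Over all alternatives the adjusted p ranged from 0.0047 to 0.169 for Ifi204 and from 0.0058 to 0.271 for Cxcl9.

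These were the 2 genes of 22180 with a limma adjusted p under 0.05, and 0 genes passed in the higher direction. At an unadjusted p under 0.05 there were 1956 genes, 8.82% of those tested where chance gives 5%, with 771 lower and 1185 higher in Stat2 KO hosts. That split depended on the scaling. It was 794 lower and 889 higher after a further quantile normalization, 1108 and 654 after median centring, and 878 and 800 after cyclic loess, which was chosen after the data were seen. The count of 1956 also depended on single arrays, with 3260 without Stat2 KO replicate 1, 1260 without Stat2 KO replicate 3, 1197 and 1177 without WT replicates 1 and 2, and 5004 with array weights. Groups did not overlap for 2958 genes, 13.3% where chance gives 10%. The adjusted count was 0 after the further quantile normalization and after cyclic loess, 257 with array weights, and 17 without WT replicate 3. It was 0 without Stat2 KO replicate 1, Stat2 KO replicate 2 or WT replicate 1, and 1 without Stat2 KO replicate 3 or WT replicate 2.

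Of the lower genes that filled the open places of the naming rule, Lifr, the receptor of leukemia inhibitory factor, differed most, by -1.64 (SE 0.385, adjusted p = 0.351). Axl, a TAM receptor tyrosine kinase that takes part in the uptake of dying cells, differed by -1.21 (SE 0.179, adjusted p = 0.133). Without WT replicate 3 the differences were -2.20 for Lifr and -1.43 for Axl, and both passed (adjusted p = 0.0076 for each, with ranges over the alternatives of 0.0076 to 0.875 and 0.0058 to 0.507). Lilrb4a, an inhibitory receptor of myeloid cells, differed by -1.18, and Pdpn, which encodes podoplanin, by -0.93, with adjusted p-values of 0.312 and 0.316. Among higher genes the small nucleolar RNA Snora75 differed by 1.17 (SE 0.354, adjusted p = 0.462), with 12.01 in Stat2 KO replicate 2 against 10.25 and 10.48 in the other Stat2 KO tumours. Without that replicate the Snora75 difference was 0.62. Gria4, a subunit of AMPA-type glutamate receptors, differed by 0.84, the kinase gene Stk24 by 0.83 and Fam81a by 0.75, with adjusted p-values of 0.312, 0.351 and 0.285. The olfactory receptor genes Olfr491, Olfr1359, Olfr38 and Olfr917 differed by 0.76, 0.73, 0.73 and 0.64, with Olfr491 at 0.51 without WT replicate 3. The cornified envelope gene Lce3d and the vomeronasal receptor gene Vmn1r170 differed by 0.67 and 0.61, with Lce3d at 0.44 without Stat2 KO replicate 3. All the genes of this paragraph had groups that did not overlap, as the naming rule required. None of them passed the adjusted threshold when all 6 arrays were used with equal weight and no replicate block. With array weights Lifr, Axl, Pdpn, Gria4, Stk24, Fam81a, Olfr1359, Olfr38, Olfr917 and Lce3d passed, and Axl also passed with a replicate block.

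**Figure D1:**
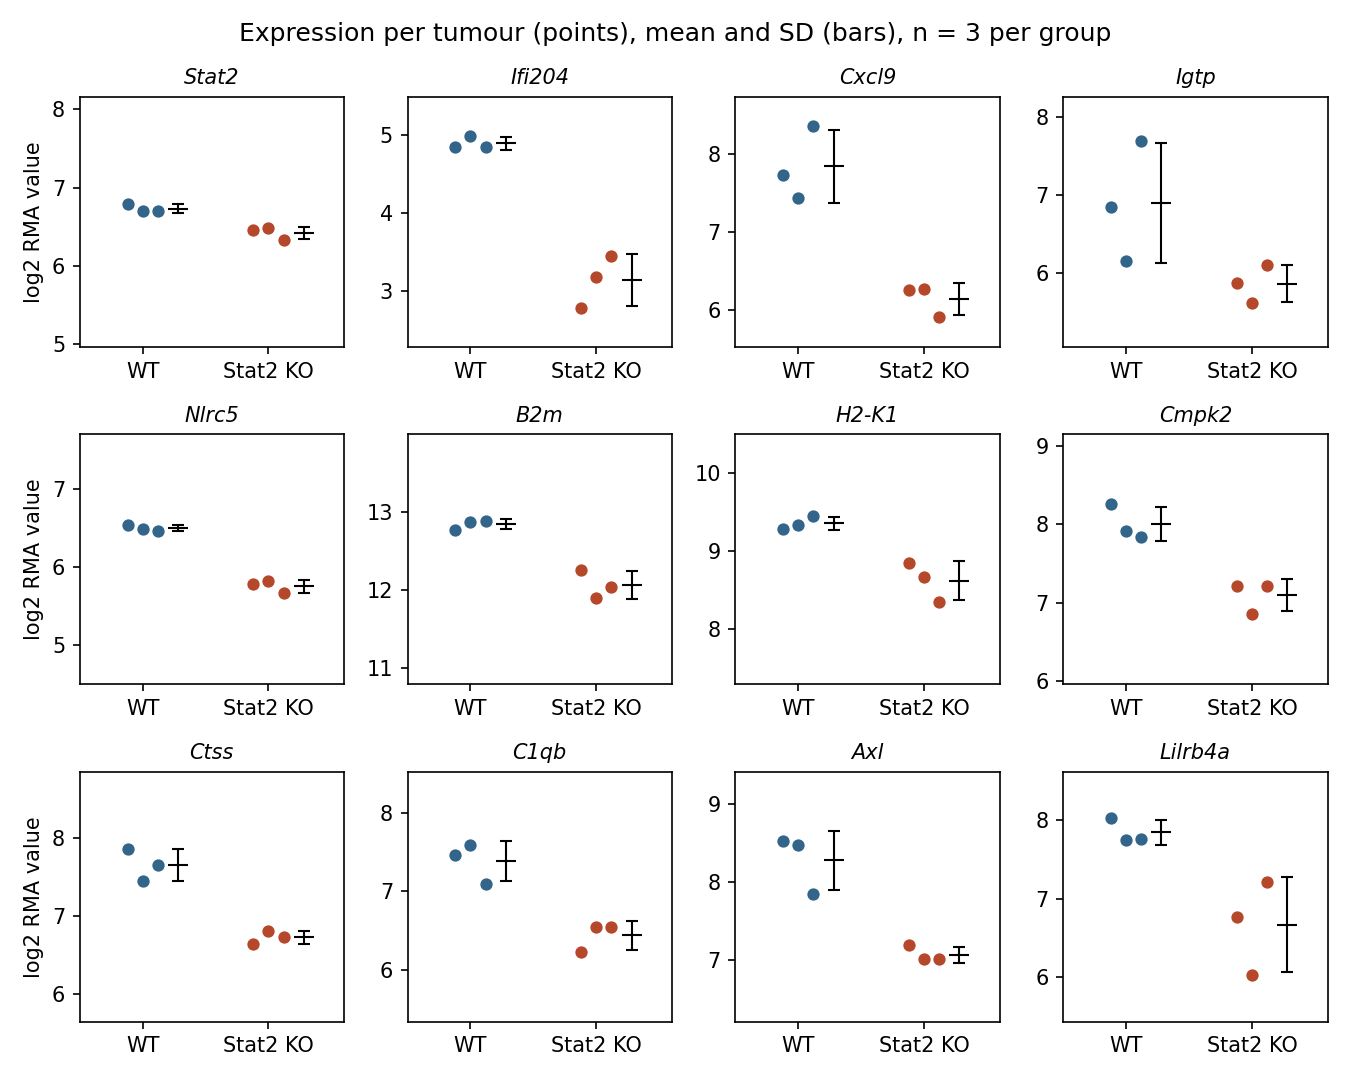
Log2 RMA values of 12 genes in each tumour, with WT hosts in blue and Stat2 KO hosts in red. Points are tumours and bars are mean and SD of 3. Each vertical axis has the same width in log2 units, centred on the values of that gene. All 12 genes were picked among those lower in Stat2 KO hosts, and none of the genes named as higher is shown. Only Ifi204 (adjusted p = 0.0298) and Cxcl9 (0.0338) passed the limma test over all genes.

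Genes induced by type I interferon were lower as a group in tumours of Stat2 KO hosts. Of 36 measured members, 32 were lower and 4 higher, with a median log2 difference of -0.22 (camera adjusted p = 1.2e-09; adjusted p = 0.30 with an estimated correlation). Random lists of matched expression had medians between -0.083 and 0.066 in 95% of draws. Ifi204 passed over all genes, and 3 members passed when adjusted over the list alone, all of them lower: Ifi204, Cmpk2 and Rsad2. Cmpk2, a mitochondrial nucleotide kinase, differed by -0.91 (SE 0.159), Rsad2, which encodes the antiviral enzyme viperin, by -0.73 (SE 0.181), and Ifit1, which binds viral RNA, by -0.59 (SE 0.178, adjusted p over the list alone = 0.0537). Outside the naming rule, the 4 higher members were Oas3 (0.13), Oasl1 (0.078), Trim30a (0.031) and Isg15 (0.028). Oas2, Dhx58 and Mx1 differed by only -0.040, -0.011 and -0.068. Isg15 and Mx1 read below 5.21, the median level of olfactory receptor genes, in both groups. The mean deviation of the list was -0.082, -0.259 and -0.091 in the Stat2 KO tumours and 0.090, 0.055 and 0.287 in the WT tumours. The list's median was -0.13 without WT replicate 3, -0.15 without Stat2 KO replicate 2 and -0.14 with array weights.

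Genes of the interferon gamma response were also lower as a group, in 15 of 20 members, with a median of -0.31 (camera adjusted p = 4.2e-07; adjusted p = 0.374 with an estimated correlation). Matched random lists ranged from -0.040 to 0.146. Cxcl9 passed over all genes and 8 members passed when adjusted over the list alone, each lower. Among the others, the immunity-related GTPases Igtp and Irgm1 differed by -1.03 (SE 0.293) and -0.98 (SE 0.199), and the chemokine Cxcl10 by -0.82 (SE 0.207). WT replicate 3 held the highest list score, 0.519 against 0.096 and 0.037 in the other WT tumours, and without it the median was -0.13 (camera adjusted p = 0.00076, range 2.4e-11 to 0.374 over the alternatives) and the difference of Igtp was -0.64.

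MHC class I presentation genes fell furthest by median among the lists tested. They were lower in 14 of 16 members with a median of -0.36 (camera adjusted p = 1.1e-09; adjusted p = 0.146 with an estimated correlation; fry adjusted p = 0.0369). The median stayed between -0.46 and -0.36 over the alternatives, and matched random lists ranged from -0.128 to 0.078. With adjustment over all genes 0 members passed, and 8 passed when adjusted over the list alone, all lower. B2m, the light chain of every class I molecule, read 12.1 ± 0.181 in Stat2 KO and 12.8 ± 0.064 in WT hosts (n = 3 each), a difference of -0.78 (SE 0.143). Nlrc5, the transactivator of class I genes, differed by -0.74 (SE 0.127), the heavy chain gene H2-K1 by -0.73 (SE 0.153) and the immunoproteasome subunit Psmb8 by -0.69 (SE 0.158). Over all genes B2m, Nlrc5 and H2-K1 passed with array weights, and B2m also passed among genes brighter than the median gene.

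MHC class II presentation genes were lower as a group with a median of -0.14 over 10 members, 6 lower and 4 higher (camera adjusted p = 0.0033; adjusted p = 0.374 with an estimated correlation). The numbers of members passing were 0 over all genes and 4 when adjusted over the list alone, all lower. These were the protease gene Ctss, which trims the invariant chain (-0.92, SE 0.143), H2-Aa (-0.85, SE 0.193), H2-DMb1 (-0.63, SE 0.152) and H2-Ab1 (-0.49, SE 0.148). The mean of H2-DMb1 was 4.66 in Stat2 KO and 5.28 in WT hosts, near or below 5.21, the median level of olfactory receptor genes. The size of its difference is therefore uncertain. Without Stat2 KO replicate 1 the median was -0.017 and the list was no longer called (adjusted p = 0.0736, range 9.1e-05 to 0.374 over the alternatives), and without Stat2 KO replicate 2 it was -0.24.

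Macrophage and monocyte markers were lower as a group in 15 of 21 members, with a median of -0.15 (camera adjusted p = 0.00027; adjusted p = 0.374 with an estimated correlation). Matched random lists ranged from -0.054 to 0.141. The numbers passing were 0 over all genes and 6 when adjusted over the list alone, all lower. The complement gene C1qb differed by -0.95 (SE 0.162), Ms4a7 by -0.83 (SE 0.186), the lysosomal glycoprotein Cd68 by -0.61 (SE 0.163) and the lysosomal protease Lgmn by -0.51 (SE 0.142). These macrophage markers moved in the same direction as the interferon and presentation lists. Without Stat2 KO replicate 3 the median was -0.22, and without WT replicate 3 C1qb passed over all genes (adjusted p = 0.0341, range 0.0187 to 0.623 over the alternatives).

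Inflammatory cytokine and chemokine genes were called lower with a small median, -0.043 over 27 members, 16 of them lower (camera adjusted p = 0.0248; adjusted p = 0.389 with an estimated correlation). Ccl8, which attracts monocytes, was the 1 member that passed when adjusted over the list alone, at -0.87 (SE 0.176), and 0 passed over all genes. Ccl3 differed by -0.44, Ccl9 by -0.45 and Ccl20 by 0.36. The median turned to 0.020 without Stat2 KO replicate 1, and the list was not called without that array, without WT replicate 3 or among genes brighter than the median gene (adjusted p = 0.128, 0.116 and 0.078, range 0.0023 to 0.389 over the alternatives).

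Fibroblast and matrix genes were lower as a group in 18 of 22 members, with a median of -0.12 (camera adjusted p = 0.00031; adjusted p = 0.389 with an estimated correlation). Dcn, the proteoglycan decorin, was the 1 member passing when adjusted over the list alone, at -0.94 (SE 0.210), and 0 passed over all genes. Lum, which encodes lumican, differed by -1.21 and the fibronectin gene Fn1 by -0.68, both with groups that overlapped and an adjusted p over the list alone of 0.0595, and Lum passed without WT replicate 3 (-1.76, adjusted p = 0.0118, range 0.0118 to 0.908 over the alternatives) and was -0.74 without WT replicate 1. The list was not called among genes brighter than the median gene (adjusted p = 0.078, range 4.7e-05 to 0.389 over the alternatives). The list's median was -0.25 without Stat2 KO replicate 1, -0.25 without WT replicate 3 and -0.081 without Stat2 KO replicate 2. Cell cycle genes were lower in 23 of 26 members with a median of -0.19 (camera adjusted p = 8.5e-06; adjusted p = 0.505 with an estimated correlation). Genes passing numbered 0 both over all genes and when adjusted over the list alone, with Mcm3 at -0.45 and Cdk1 at -0.32. Random lists as bright as the cell cycle genes had medians from -0.175 to -0.037, and the list's median was -0.10 without Stat2 KO replicate 2 and -0.28 without Stat2 KO replicate 1.

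Melanocyte and melanoma markers were lower in 16 of 19 members with a median of -0.13 (camera adjusted p = 0.0066; adjusted p = 0.591 with an estimated correlation), inside the range of equally bright random lists, -0.177 to -0.012. Members passing numbered 0 over all genes and 0 when adjusted over the list alone, and Ednrb, the endothelin receptor of melanocytes, differed by -0.33, with -0.15 without WT replicate 1 and -0.19 without Stat2 KO replicate 2. Without Stat2 KO replicate 2 the median was 0.0096 (adjusted p = 0.936, range 0.00022 to 0.936 over the alternatives), and the call was also lost after cyclic loess (0.123), with array weights (0.117) and among genes brighter than the median gene (0.162). Without WT replicate 1 it was -0.073 (adjusted p = 0.161), and it was -0.23, -0.20 and -0.20 without Stat2 KO replicates 1 and 3 and WT replicate 3. Immediate early and heat shock genes were lower in 11 of 16 members with a median of -0.17 (camera adjusted p = 0.0248; adjusted p = 0.515 with an estimated correlation). Ier2 differed by -0.33, with -0.20 without WT replicate 2, and 0 members passed in either adjustment. The call of this list was lost after quantile normalization and cyclic loess (adjusted p = 0.0691 and 0.0798, range 0.00089 to 0.515 over the alternatives), among genes brighter than the median gene (0.330), without Stat2 KO replicate 3 (median -0.037) and without WT replicate 2 (median -0.066).

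Markers of T cells, neutrophils and skeletal muscle were higher as groups in Stat2 KO hosts at the preset correlation, with medians inside the range of random lists as dim as they were. After quantile normalization their adjusted p-values were 0.245, 0.204 and 0.204, so 0 of the 3 were called there. Over all alternatives they ranged from 0.0094 to 0.515, 0.0049 to 0.515 and 0.0015 to 0.566. T cell genes were higher in 15 of 19 members with a median of 0.089 that turned to -0.012 after cyclic loess (camera adjusted p = 0.0306; adjusted p = 0.515 with an estimated correlation; matched range 0.017 to 0.196). Cd28 and Ctla4, a costimulatory and an inhibitory receptor, differed by 0.46 and 0.45, and 0 members passed in either adjustment. The T cell median was 0.032 without Stat2 KO replicate 2, 0.035 without WT replicate 1 and 0.15 without Stat2 KO replicate 1, and without Stat2 KO replicate 3 it was 0.090 with an adjusted p of 0.0805. Neutrophil genes were higher in 15 of 17 members with a median of 0.13 (camera adjusted p = 0.0248; adjusted p = 0.515 with an estimated correlation; matched range 0.012 to 0.206). S100a8 differed by 0.50, with 0.32 without WT replicate 3, and 0 members passed in either adjustment. The neutrophil call was lost without Stat2 KO replicate 2 (0.10) and without WT replicate 1 (0.092), and the median was 0.20 without WT replicate 3. Muscle genes were higher in 13 of 18 members with a median of 0.13 (camera adjusted p = 0.0309; adjusted p = 0.566 with an estimated correlation; matched range 0.0051 to 0.187). The fast myosin gene Myh4, at 0.60 (SE 0.142), passed when adjusted over the list alone and 0 passed over all genes. The muscle call was lost without Stat2 KO replicates 2 or 3 and without WT replicates 1 or 3, with medians of 0.085, 0.12, 0.11 and 0.16, and the median was 0.20 without Stat2 KO replicate 1.

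The remaining 7 tested lists were not called at the preset correlation. Medians were 0.14 for NK and cytotoxic effectors (camera adjusted p = 0.057), 0.105 for B and plasma cells (0.136), 0.078 for dendritic cells (0.368), -0.029 for endothelial cells (0.411), 0.051 for keratinocytes (0.368), -0.021 for adipocytes (0.614) and -0.0043 for hypoxia and glycolysis (0.888). The hypoxia list has a mean of 0.027, opposite in sign to its median, and its median turned to 0.061 after quantile normalization. Without Stat2 KO replicate 3 it was 0.111 and the list was called higher (adjusted p = 0.0373, range 0.037 to 0.972 over the alternatives). The keratinocyte median turned to -0.024 after median centring. Without Stat2 KO replicate 1 the NK, B cell and dendritic lists were called higher (medians 0.197, 0.195 and 0.170), as was the NK list without WT replicate 3 (0.203), and the B cell and dendritic lists were called higher with array weights (0.1707 and 0.1496). The B cell median was 0.212 without WT replicate 3, 0.063 without Stat2 KO replicate 2 and 0.059 without WT replicate 2, and that of keratinocytes was 0.122 and 0.109 without Stat2 KO replicates 3 and 1 and 0.034 without Stat2 KO replicate 2. As single arrays were left out, medians ranged from -0.024 to -0.0064 for endothelial cells, the smallest without WT replicate 3, and from -0.106 without WT replicate 3 to 0.023 without Stat2 KO replicate 1 for adipocytes. Among NK and effector genes, the chemokine Ccl5 differed by -0.35 and the transcription factor Tbx21 by 0.37, with 0.24 without Stat2 KO replicate 2. In the dendritic list Fscn1, which encodes fascin of mature dendritic cells, differed by -0.66 and the lectin gene Clec10a by 0.62, and these 2 members passed when adjusted over the list alone. In the 6 other lists 0 members passed that way, and 0 passed over all genes in any of the 7. Of the red blood cell list 3 genes were measured, too few for a test: Slc4a1 differed by 0.38, Epb42 by 0.13 (0.077 without Stat2 KO replicate 2 and 0.028 after cyclic loess) and Klf1 by -0.021.

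Altogether 13 of the 20 tested lists were called by camera at the preset correlation, 10 lower and 3 higher. Splits of the tumours that mixed the host genotypes called up to 11 lists at that correlation. With an estimated correlation 0 were called by camera, with 2 at an unadjusted p under 0.05, and fry called 1, MHC class I presentation. When fry asked for changes in either direction rather than one way on balance, it called 6. Medians of lists also moved with the scaling: after cyclic loess they were -0.23 for MHC class II, -0.12 for cell cycle, 0.036 for NK, 0.014 for B cell and 0.0041 for dendritic genes, and after median centring -0.22 for macrophages and -0.20 for fibroblasts. Among genes brighter than the median gene that of macrophages was -0.33. With array weights, members of other lists that passed over all genes were Cmpk2, Ctss, Ccl8, C1qb, Ms4a7, Cd68, Lgmn, Fscn1, Fn1, Cd28 and Myh4. Array scores of 5 lists had all Stat2 KO tumours below all WT tumours: type I interferon, interferon gamma, MHC class I, MHC class II and macrophages (exact permutation p = 0.1 for each, the smallest possible).

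**Figure D2:**
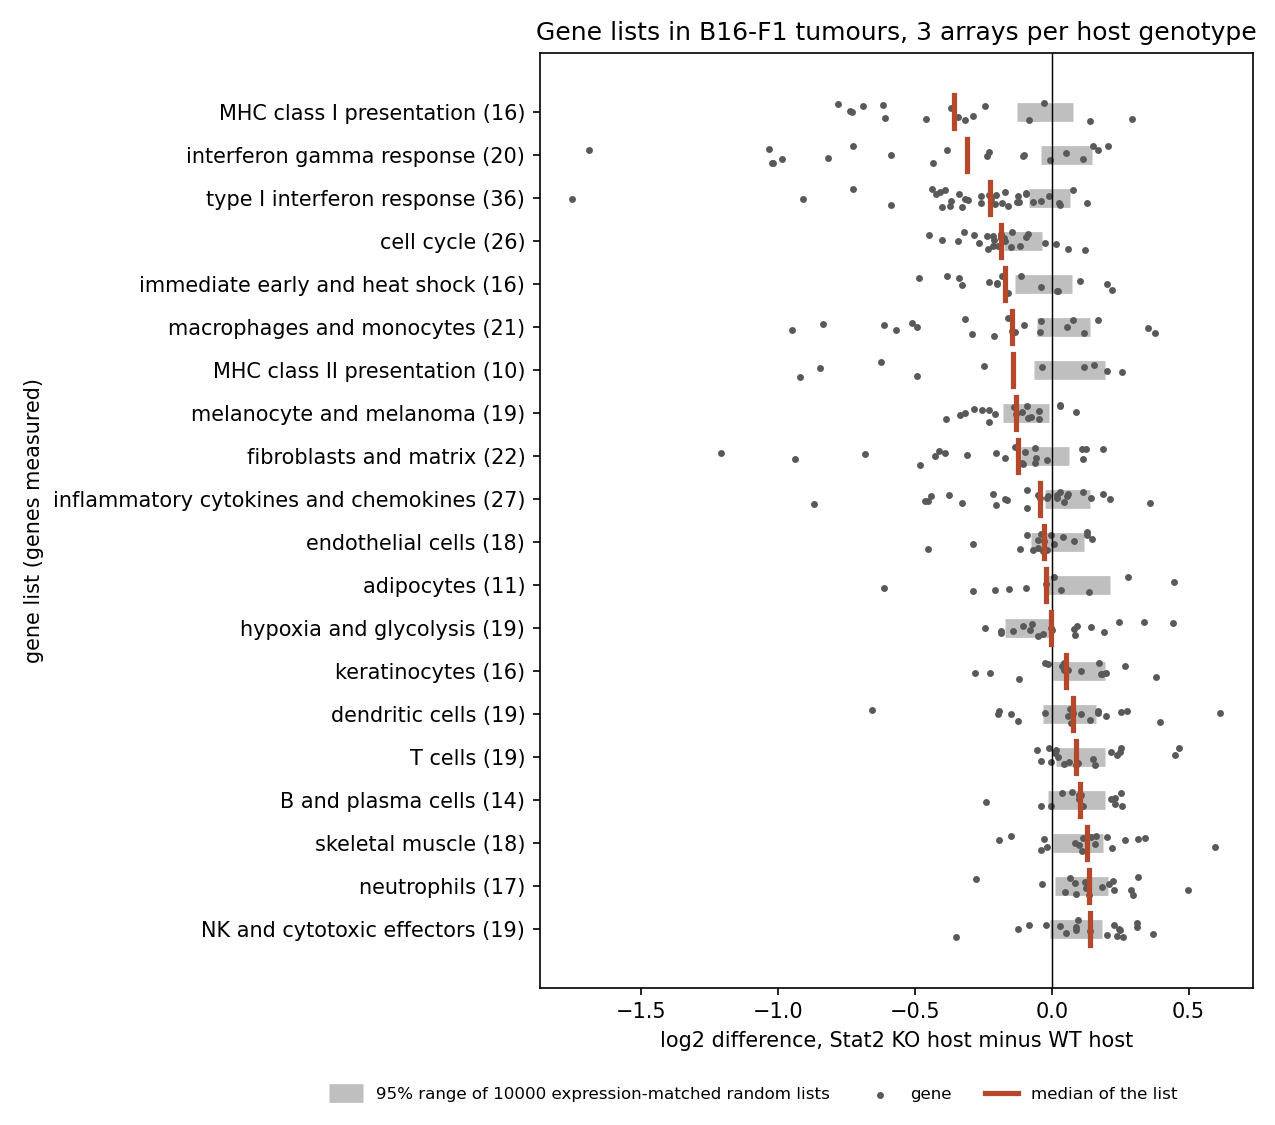
Log2 difference, Stat2 KO host minus WT host, of each gene (points) in 20 lists with the number of genes measured, the median of each list (red) and the 95% range of medians of 10000 random lists of matched expression (grey). The medians of MHC class I (-0.36), interferon gamma (-0.31) and type I interferon (-0.22) genes lie left of their grey ranges. Those of MHC class II, macrophage, immediate early, inflammatory, cell cycle and fibroblast genes do so too, by smaller margins. The random lists hold genes drawn one by one, so the grey ranges leave out the spread that correlated genes of a list share. The T cell median (0.089) turned to -0.012 after cyclic loess, and those of hypoxia and keratinocyte genes also change sign with the scaling.

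In the difference between the groups, dim genes tended to be higher and bright genes lower in Stat2 KO hosts, but not in each array. The median log2 difference was 0.11 over the genes below the median expression and -0.068 over those above it, and the Spearman correlation of difference with mean expression was -0.416 across genes, which are not independent replicates. Stat2 KO replicate 1 ran the other way over most of the range. In bins of genes at median expression 5.53 and 8.78 it deviated from the gene means by -0.037 and 0.097. Stat2 KO replicates 2 and 3 deviated there by 0.1375 and -0.2025 and by 0.075 and -0.046, and WT replicate 3 by 0.014 and -0.030. Stat2 KO replicate 2 stood furthest from the rest on the first principal component, which held 40.6% of the variance, at 34.3 against values from -28.2 to 13.2 in the other tumours. Without it the medians were 0.071 and -0.035, without Stat2 KO replicate 1 they were 0.155 and -0.117, and after quantile normalization 0.043 and -0.028, after median centring 0.034 and -0.143, and after cyclic loess 0.022 and -0.025.

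**Figure D3:**
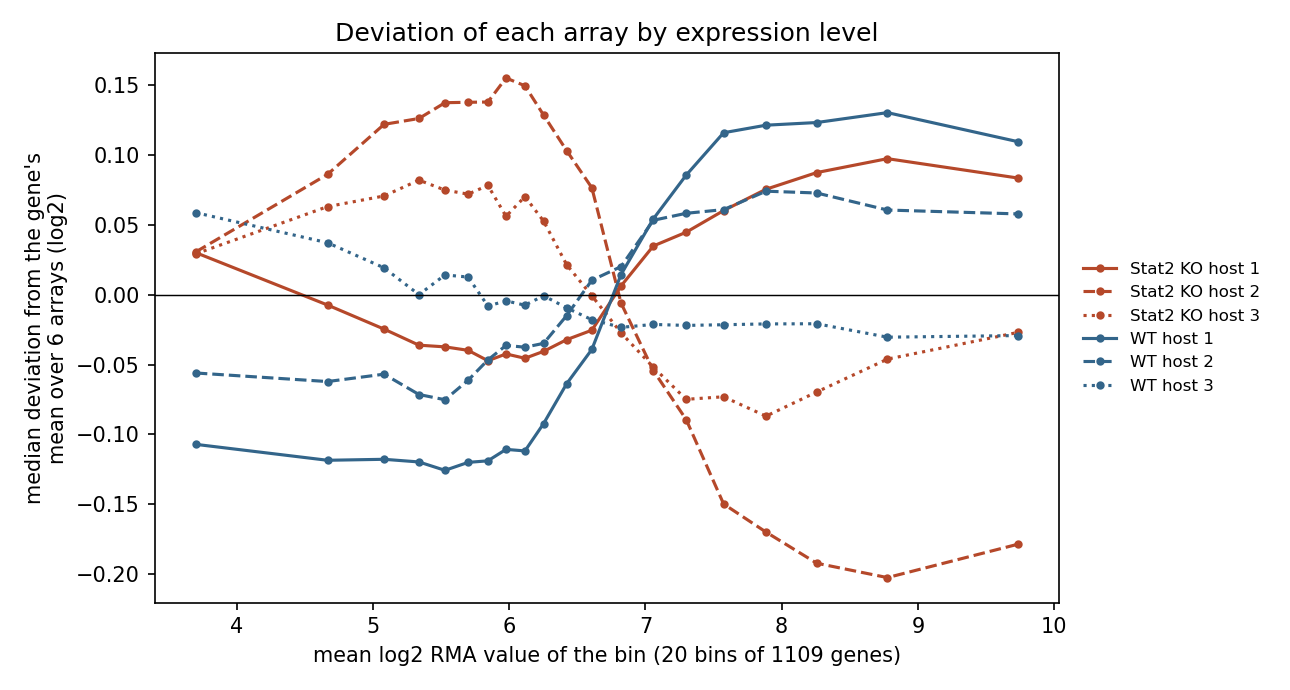
Median deviation of each array from the gene means over all 6 arrays (log2), in 20 bins of 1109 genes ordered by mean log2 RMA value, with Stat2 KO hosts in red and WT hosts in blue. Stat2 KO replicate 2 is above the mean among dim genes and below it among bright genes, and WT replicate 1 runs the opposite way. Stat2 KO replicate 1 and WT replicate 2 also run the opposite way over most bins, by smaller margins. WT replicate 3 stays near the mean in most bins.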

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

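Cyclic loess was chosen after the results had been seen. The count of 2 genes was 0 after a further quantile normalization, 0 after cyclic loess, 0 over all probe sets, 1 without the trend and 257 with array weights (129 lower, 128 higher), ranged from 0 to 17 as single arrays were left out, and was 21 at an unadjusted p under 0.05 and at least 2-fold. Simulated changes of 1 log2 unit were recovered in 98 of 100 genes. That simulation had independent genes and many planted changes, with 216 calls, which makes the adjusted threshold easier to pass. In the tumours Lifr at -1.64 and Axl at -1.21 did not pass. The simulation therefore cannot show whether array number limits this count. The 13 lists called became 5 among genes brighter than the median gene, 8 after cyclic loess, 0 with an estimated correlation and 1 by fry. The type I interferon median of -0.2247 had adjusted p-values of 0.30 by camera with an estimated correlation and 0.245 by fry. Its call held in the other 14 alternatives, with medians from -0.30 to -0.13. Those 14 all kept the preset correlation of 0.01, whereas the correlation estimated for this list was 0.119, so they do not test that setting. The Stat2 difference ranged from -0.39 to -0.27 over 15 alternatives, none of which passed the threshold. Signs turned for hypoxia genes (0.06141 after quantile normalization, 0.08767 after cyclic loess, -0.1118 to 0.1113 as arrays were left out), keratinocytes (-0.0002875 after quantile normalization, -0.02352 after centring, -0.0212 after cyclic loess), dendritic cells among brighter genes (-0.1475), endothelial cells with array weights (0.005158) and T cells after cyclic loess (-0.01245). Leaving out arrays gave -0.07318 to 0.0204 for inflammatory genes, -0.1062 to 0.02299 for adipocytes, -0.2258 to 0.009632 for melanoma markers and -0.06579 to 0.04451 for Klf1. Among brighter genes, lists with too few bright members gave no value, and robust eBayes gave none for lists. For all of these the cause was not tested. Signal over background was not used here, so what it limits for dim probe sets was not analysed.

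With the replicate number as a replicate block the gene count was 3 and the list count 14. Deviations of same-numbered tumours correlated at 0.240, 0.079 and 0.030, so the numbers were not taken to pair the samples, and Stat2 KO replicate 2 correlated best with WT replicate 3 (0.205). Axl and the NK list passed the threshold under the block, and no other call changed.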

Other observations

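Cyclic loess, the 5 added lists, their reduced forms and the tests on olfactory and other receptor families were chosen after the first gene tables had been seen, and the test against macrophage genes was written after its values were known.

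Genes of a pan-leukocyte list were lower in tumours of Stat2 KO hosts, in 14 of 18 members with a median of -0.14 (camera adjusted p = 9.7e-05 over the 5 added lists, p = 0.0145 with an estimated correlation). The list includes Fcer1g and Tyrobp (-0.35), which are found mainly in myeloid and NK cells rather than in most leukocytes. Fcer1g, the shared signalling chain of Fc receptors, differed by -0.62 (SE 0.137), Lcp1 by -0.66 and Cd53 by -0.41. Lcp1 read 6.73 in Stat2 KO replicate 2 against 7.75 and 7.40 in the other Stat2 KO tumours. Cyba, a subunit of the NADPH oxidase, differed by 0.67 (SE 0.297) with groups that overlapped. It read 8.31 in WT replicate 3 against 7.06 and 7.02 in the other WT tumours. Coro1a, Cd37 and Rac2 differed by only 0.051, 0.011 and -0.015, and Ptprc, which encodes CD45, by -0.35 with groups that overlapped. Phagocytic receptor and complement genes had a median of -0.20, with 20 of 29 lower, but the list was drawn up knowing the values of 4 members and holds 7 macrophage markers, so its tests are not independent evidence (camera adjusted p = 1.2e-06; p = 0.0103 with an estimated correlation). Without those 10 genes the median of the other 19 was -0.16, with 11 lower (camera p = 0.0091; p = 0.0694 with an estimated correlation). Members included the scavenger receptor Msr1 at -0.88 (SE 0.170) and C3ar1 at -0.44. These genes were picked as examples after their values were seen, and none passed over all genes. Of the phagocytic list, 1 gene is shared with the pan-leukocyte list.

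Type I interferon genes themselves had a median of 0.024 over 16 genes that turned to -0.051 after median centring and -0.018 after cyclic loess (camera adjusted p = 0.561), and Ifnb1 differed by 0.24 (SE 0.170). Ifnb1 read 5.06 in Stat2 KO and 4.82 in WT hosts, below 5.21, the median level of olfactory receptor genes. Ifnab, Ifna9, Ifna11, Ifna13, Ifna16 and Ifnk also read below it in both groups, and the remaining members read above it. For the genes below it, signal above background was not shown, so the median does not show that interferon expression was equal. Interferon receptor and signalling genes were lower in 10 of 10 members, with a median of -0.13 (camera adjusted p = 0.0071; p = 0.234 with an estimated correlation) that equally bright random lists often reached, at percentile 30.3. That median was -0.051 after quantile normalization, -0.042 after cyclic loess and -0.208 after median centring. A list of TGF-beta pathway genes and targets, chosen knowing Tgfbi and Tgfb3, had a median of -0.074 (camera adjusted p = 0.0018, p = 0.0238 with an estimated correlation) at percentile 20.5 of its matched random lists. The list holds ligands and receptors such as Tgfb1 and Tgfbr2, and 3 of its genes also stand in a fixed list. Its median was -0.035 after quantile normalization, -0.028 after cyclic loess and -0.148 after median centring. Without Tgfbi and Tgfb3 it was -0.070 (camera p = 0.0434, p = 0.0952 with an estimated correlation). Tgfbi differed by -0.70 (SE 0.129) and Tgfb3 by -0.80 (SE 0.164).

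The lower interferon and MHC class I genes were weighed as 1 pattern of 72 pooled genes with a median of -0.27. An intensity-dependent shift between arrays was argued against: after cyclic loess the median was -0.3026, below the 95% range of matched random lists, -0.054 to 0.038. A smaller share of leukocytes in these tumours stays open, as the pan-leukocyte median lay 0.1357 above the pooled one (bootstrap 95% interval over genes -0.121 to 0.260). The pan-leukocyte list includes genes found mainly in myeloid and NK cells, so it is an uneven measure of all leukocytes. T cell, NK and neutrophil markers were higher in 15 of 19, 15 of 19 and 15 of 17 members, with medians inside the range of random lists as dim as they were. The hypothesis that loss of the host's STAT2 lowers interferon-driven genes more than other genes of the same cells also stays open, with the pooled median -0.1271 from that of macrophage genes (interval -0.301 to 0.087). Lower interferon signalling in host cells and fewer such cells cannot be told apart here, since each array reads a whole tumour. Both intervals include 0, but they were drawn over genes that can vary together. They do not measure the spread between tumours, so they could not decide between these causes. The arrays do not separate host cells from melanoma cells either. The larger tumours that the submitters describe in Stat2 KO hosts were not taken into account.

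Olfactory receptor genes were higher in Stat2 KO hosts, 903 of 1105, with a median of 0.22, and of 0.18 after quantile normalization, 0.148 after median centring and 0.152 after cyclic loess. A shift of all dim probe sets was argued against, as the median of 0.2231 lay above the matched range of 0.079 to 0.103. The array of Stat2 KO replicate 2 alone was argued against too, since the median was 0.2382 without it, 0.254 without Stat2 KO replicate 1 and 0.171 without Stat2 KO replicate 3. A higher hybridization background of genes silent in tumours may contribute, as the pooled vomeronasal type 1 and taste receptor type 2 genes had a median of 0.123, above the upper bound of 0.111 of their matched range, though vomeronasal type 2 genes, at 0.0996, were at percentile 75.5 of theirs. The support is weak, since the pooled median was 0.073 after quantile normalization, 0.048 after median centring and 0.0524 after cyclic loess, where the upper bound was 0.0510 and vomeronasal type 1 genes alone were at percentile 89.8, and no biological explanation was tested.

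Of the 10 splits of the 6 tumours into 3 and 3, 1 called as many genes as the real one, the real split itself, with 2 genes against a highest other count of 0. For lists, 1 split, the real one, called as many, 13 against a highest other count of 11. The other splits mix the host genotypes and called from 0 to 11 lists at the preset correlation. With an estimated correlation 0 lists were called in any split. A list call at the preset correlation therefore does not by itself single out host genotype. By median the real split was not the furthest for type I interferon genes, at 0.2247 in size against 0.2399 for Stat2 KO replicate 1 with WT replicates 1 and 3 against the rest. It was the furthest for MHC class I genes, at 0.3563 against 0.2029 in that same split, the largest of the others. The splits are too few for a share under 0.05. Stat2 KO replicate 1 with WT replicates 1 and 2 against the rest gave 3775 genes at an unadjusted p under 0.05 where the real split gave 1956. It was the largest such count among the other splits, with 0 genes after adjustment. The unadjusted count therefore does not single out host genotype, and what lies behind the larger count was not tested.

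Xist, the RNA of the inactive X chromosome, read 4.97, 5.29 and 5.06 in Stat2 KO tumours and 6.13, 5.94 and 5.05 in WT tumours. Of Y-linked genes, in the same order, Eif2s3y read 3.62, 3.57 and 3.56 against 3.12, 3.46 and 3.98, Uty 4.30, 4.29 and 4.35 against 4.16, 4.10 and 4.42, and Kdm5d 3.89, 4.37 and 3.97 against 3.91, 4.14 and 4.05. Eif2s3y and Uty were lowest in the 2 tumours with the highest Xist, all 3 Y-linked genes were dim, and host sex is not given in the labels, so an unequal sex of the groups was not excluded.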
